A study of Caenorhabditis elegans with 4 samples.

How the data were processed

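Peak lists from ChIP-seq of CEY-2 fused to GFP in whole L4 worms were analysed, from 4 libraries of 3 biological replicates. Chromatin was sonicated and precipitated with an antibody against GFP, per the labels. The lists were called by the authors against a control that was not analysed here, and the reads were not used here. There were 10 lists, 5 for each of the builds ce10 and ce11: 1 for each biological replicate, 1 for the pooled replicates and 1 of peaks that passed the authors' IDR threshold. The 2 technical libraries of replicate 2 were merged by the authors into 1 alignment and count as 1 replicate. The peak caller, the aligner and their versions are not given in the sources used here.

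Each deposited list gives a signal value per peak, which is the peak caller's own value against the control and was used only to rank, filter and describe peaks within 1 list. Each also gives the −log10 of a q-value, per the authors' format, which reaches a ceiling: 657 peaks of the pooled ce11 list share the highest value, 3.12, and all 611 IDR peaks have it. It was therefore not used to rank peaks. The lists of replicates 1 and 2 hold exactly 30000 peaks each. No read counts were given, so depth and the counting error of single peaks are unknown.

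Coordinates are those of build ce11 (WBcel235), whose chromosome lengths fit the reference sequence used, and are written 1-based. Lists in ce10 were never converted, and were used as an alternative where no gene or sequence is needed, with shifts drawn within the ce11 lengths. Genes came from Ensembl release 115. The 12 mitochondrial coding genes carry symbols, taken for those without one from the RefSeq gene of the same assembly that covers at least 80% of the same bases; mitochondrial tRNA and rRNA genes are given by identifier.

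A summit is the peak start plus the caller's summit offset in bp, as deposited. Summits were assigned to the first fitting class of promoter (500 bp upstream of a gene start, piRNA genes left out), 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron, 500 bp downstream and intergenic. Class shares and overlaps between replicates (summits within 200 bp) were compared with 10000 circular shifts, in which all summits of a chromosome move by 1 random offset. A gene had a peak where a summit lay within 500 bp of its start. The 22 gene lists were tested with Fisher's exact test, coding lists against 19985 protein-coding genes and RNA lists against 31563 genes without piRNAs (the piRNA list against all genes). Genes near each other can share 1 peak and are then not independent.

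The 11 sequence words were searched on both strands within 100 bp of the summit and in 1 flank window 500 bp away, on a side drawn at random and anew for each set of peaks, and compared with the exact McNemar test. Ratios of these counts have 0.5 added to each count. GC content was compared with a sign-flip permutation test and signal by class with a permutation test of medians, 100000 draws each. Chromosome shares were tested with the exact binomial test. All tests were two-sided except those for overlap, for clusters and for the order of mitochondrial heights, and p-values were adjusted by Benjamini-Hochberg within each family. Intervals are exact (Clopper-Pearson) 95% intervals and cover counting error only. Peaks are not replicates, so these p-values describe the lists of this experiment.

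The gene lists, words, planned tests and the rule for named genes were fixed before the data were examined. The rule took the genes nearest to the 25 highest IDR peaks, the 4 members with the highest signal of each passing list, the 2 highest of each other list, and cey-1, cey-2, cey-3, cey-4, lin-28 and unc-119. Names outside it are the remaining ribosomal protein genes, F54E7.10, WBGene00022903, COX3 and the genes at clusters of peaks in the closing section, chosen after their values were seen. Members of the piRNA list, which passed with a lower share than other genes, were not named, a departure from the rule. Alternatives varied the window, the overlap distance, the signal threshold, the build and the expectation, and used each replicate's own top 611 peaks. Those restricted to nuclear peaks, and several others named in the closing section, were chosen after seeing the data. So was the ratio of shares, which replaced the odds ratio in the description of gene lists and left the p-values unchanged.

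The statistics were tested on simulated data: in 20 sets of 600 random summits, 2 of 440 list tests, 2 of 220 word tests, 0 of 160 class tests, 1 of 20 overlap tests, 2 of 20 GC tests and 1 of 20 signal tests passed. In 20 sets with planted effects, each effect was called in 20 of 20, and 200 to 203 of the 200 planted shared summits were found, the excess being chance neighbours. Apart from planted effects, summits were drawn evenly over the nuclear chromosomes, without mitochondrial peaks, clusters or a preference for gene starts. Planted GC differences and all signal values were drawn as random numbers. These rates may therefore not hold for the real lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.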

Results

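Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the DNA recovered with CEY-2, a Y-box protein with a cold shock domain, in whole L4 hermaphrodites of Caenorhabditis elegans. The worms belonged to strain OP358, in which an integrated transgene carries CEY-2 with a C-terminal GFP-FLAG tag on an unc-119 mutant background, and the tagged protein was recovered with an antibody against GFP. The series held 4 libraries from 3 biological replicates, replicate 2 having 2 technical libraries that were merged by the authors. All libraries formed 1 group, so the comparisons were between replicates, between peaks and shifted positions, and between gene groups. The lists give no read counts, and the depth of each library is therefore unknown.

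The authors' thresholded list for genome build ce11 held 611 peaks, which fell into 599 distinct regions. It was made with the irreproducible discovery rate (IDR), which measures how well the ranks of peaks recur between replicates. A peak on the list did not have to rank high in each replicate. The peaks had a median width of 390 bp, and the caller's signal value ran from 35.9 to 2297 with a median of 45.7. All 611 were also the 611 highest peaks by signal of the 25484 in the pooled list. The lists of replicates 1, 2 and 3 held 30000, 30000 and 21628 peaks, including background regions kept as input for the IDR step. In build ce10 the thresholded list held 528 peaks.

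The strongest peaks lay on the mitochondrial genome. Of the 611 peaks, 25 were mitochondrial, and they included the 17 highest and 18 of the top 20. The highest had a signal of 2297 and spanned positions 4282 to 5171, with its summit at 4719 inside the coding sequence of CYTB (WBGene00000829), the gene for cytochrome b. The next, with a signal of 1530, spanned positions 11599 to 12596, with its summit at 12456 inside ND5 (WBGene00010967), a subunit gene of respiratory complex I. Both held ranks 1 and 2 in each of the 3 replicates, and the summit of the highest peak lay at 4756, 4714 and 4732 in replicates 1, 2 and 3.

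Other high mitochondrial summits lay in ND4 (signal 751), COX3 (735), ND1 (666), ATP6 (536), COX1 (525) and ND2 (426). A summit with a signal of 654 lay in the rRNA gene WBGene00014454, and one of 481 in ND3. The remaining mitochondrial genes nearest to the 25 highest peaks were ND6, COX2 and the tRNA genes WBGene00014458, WBGene00014466, WBGene00014467 and WBGene00014471. The mitochondrial peaks covered 62.4% of the 13794 bp molecule in the thresholded list. Among the top 611 peaks of replicates 1, 2 and 3 there were 27, 23 and 23 mitochondrial peaks, covering 54.3%, 46.1% and 48.2%, and in each replicate all of the top 20 peaks were mitochondrial. Several summits shared 1 interval, so that the 25 peaks made up 15 distinct regions. No test was made of this excess, since the control used for calling was not analysed here.

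**Figure D1:**
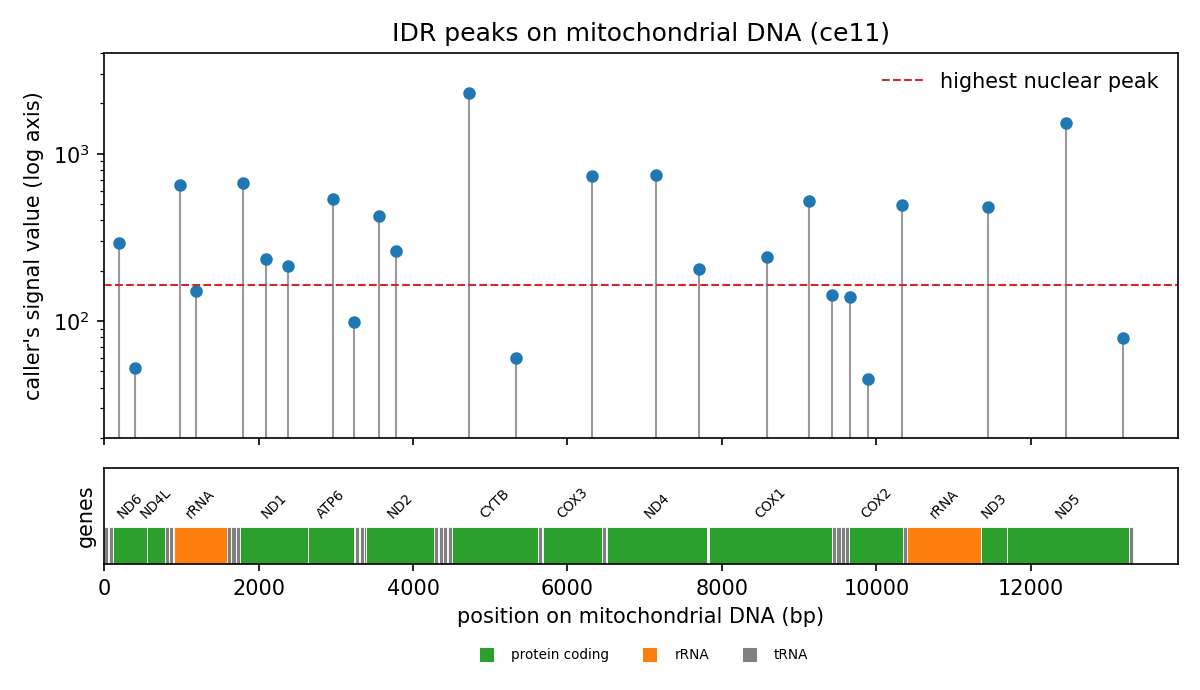
The caller's signal value (log axis) of each of the 25 mitochondrial IDR peaks is plotted at its summit position in bp, above a map of the mitochondrial genes. The CYTB summit reaches 2297 and the ND5 summit 1530, and the dashed line marks the highest nuclear peak at 163.

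The highest nuclear peak had a signal of 163 and lay on chromosome III at 3867466 to 3867648, with its summit at -293 bp from the start of rpl-3, which encodes a protein of the large ribosomal subunit. It was followed by a peak on chromosome IV at 8527695 to 8527875 (signal 157) in an intron of pkg-2. The next lay at the noncoding RNA gene D2023.12 on chromosome V (132), at -1533 bp from the start of the nuclear receptor gene nhr-21 on chromosome II (122), and at -15 bp from the start of H12C20.7 on chromosome V (122). These 5 nuclear peaks complete the 25 highest, and each ranked among the top 67 of every replicate's own list. The median nuclear signal was 44.7.

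No thresholded peak lay at the loci carried by or rescued with the transgene. Within 20 kb of cey-2 (chromosome I, 5619569 to 5620669) the best peak ranked 4757 in the pooled list and 2369, 4061 and 2642 in replicates 1, 2 and 3. Around unc-119 (chromosome III, 10902641 to 10908935) the best ranks were 4220 in the pooled list and 4844, 6621 and 4876 in the replicates. The family members cey-1, cey-3 and cey-4 also had no thresholded peak within 20 kb. The cold shock domain gene lin-28 (chromosome I, 8407630 to 8410804) had 1 within 20 kb, at rank 157, and none within 500 bp of its start. Ranks describe positions within 1 list, and no test was made.

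The replicates placed their highest peaks at many of the same sites. Of the top 611 peaks of replicate 1, 222 (36.3%) had a top 611 summit of replicate 2 within 200 bp, against 2.78% when summits were shifted along their chromosomes. The shares were 34% against 2.84% for replicates 1 and 3, and 38.5% against 2.45% for replicates 2 and 3. In a one-sided circular-shift permutation test of 10000 draws each of the 3 pairs gave p = 0.0001 (adjusted p = 0.0001), the smallest possible. Without mitochondrial peaks the shares were 34.5%, 32.4% and 37.5%, against 0.240%, 0.243% and 0.243%, an alternative chosen after the data were seen.

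Of the 611 thresholded peaks, 590, 606 and 570 had a summit within 200 bp in the full lists of replicates 1, 2 and 3, and 544 (89%) had one in all 3. Fewer ranked high everywhere: 124 (20.3%) were among the top 611 of all 3 replicates, 209 of 2, 239 of 1 and 39 of none. Replicate 2 had 404 of the 611 in its top 611, replicate 1 had 307 and replicate 3 had 318. Across matched peaks, which are not independent replicates, Spearman's rho of the signal values was 0.174 for replicates 1 and 2, 0.237 for 1 and 3, and 0.256 for 2 and 3. Among nuclear peaks it was 0.105, 0.152 and 0.196. The thresholded peaks are the highest of the pooled list, and such a selection by itself lowers rho, so these values do not describe the full lists.

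Summits lay upstream of gene starts more often than shifted summits, and rarely in coding exons. Promoters, taken as the 500 bp upstream of an annotated gene start, held 215 of 611 summits (35.2%), 2.20 times the 16% ± 1.44 (SD over 10000 shifts) of shifted summits. Coding exons held 13 (2.13%) against 23.5% ± 1.81, and 8 of these 13 were mitochondrial, leaving 5 of 586 nuclear summits (0.853% against 23%). Introns held 129 (21.1% against 30.6%) and intergenic sequence 163 (26.7% against 18%). In two-sided circular-shift permutation tests each of these 4 classes had p = 0.0002, the smallest possible, and an adjusted p of 0.0004 over the 8 classes.

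Exons of noncoding genes held 27 summits (4.42% against 2.78%) and the 500 bp downstream of genes 43 (7.04% against 4.97%), both with an adjusted p of 0.0411 in the same permutation test. Neither passed among the peaks at or above the median signal, where the adjusted permutation p was 0.469 for noncoding exons and 0.923 for downstream sequence. Noncoding exons also failed in replicates 1 and 3 alone (adjusted permutation p = 0.904 and 0.224) and downstream sequence in replicate 2 alone (0.32). With promoters of 1000 bp neither passed, and with promoters of 250 bp downstream sequence did not. The 12 summits in 5′ UTRs (1.96% against 1.51%, adjusted permutation p = 0.441) and the 9 in 3′ UTRs (1.47% against 2.55%, adjusted p = 0.122) did not pass. In the list of replicate 1 alone the 3′ UTR share was 4.26% and lay above its shifted share, with an adjusted permutation p of 0.0304, and in replicate 2 alone the 5′ UTR share passed (2.95% against 1.51%, adjusted p = 0.0157). Promoter and other peaks had median signals of 46.1 and 45.3, a difference of 0.871 (two-sided permutation p = 0.672) that changed sign under 5 of 7 alternatives.

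**Figure D2:**
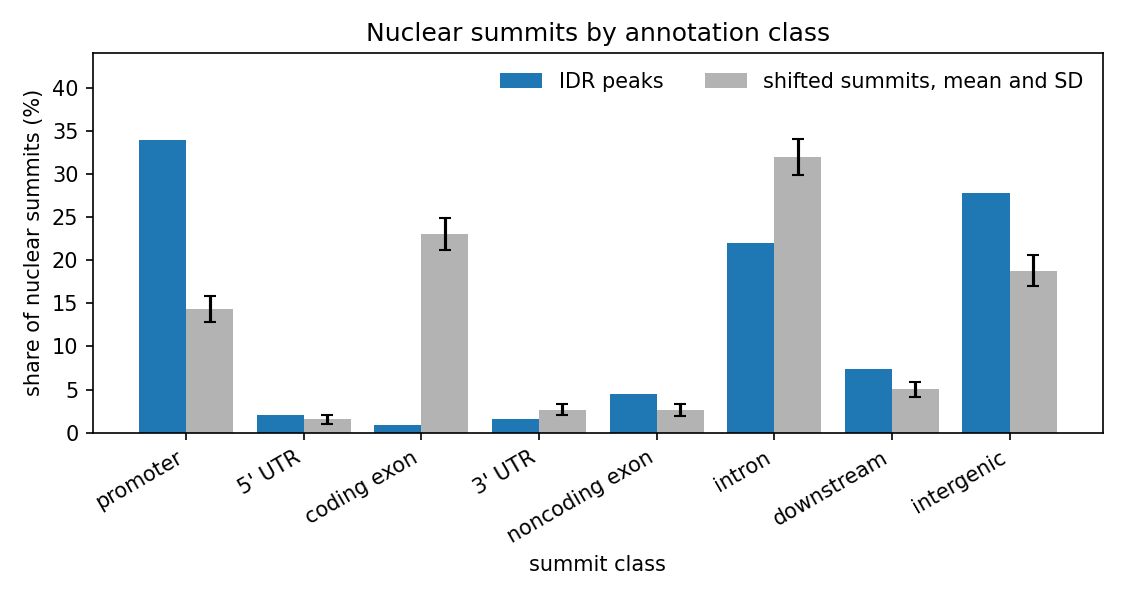
Bars give the share of the 586 nuclear summits in each annotation class (%), beside the mean and SD of shifted summits. Promoters stand at 34% against 14.3% and coding exons at 0.853% against 23%.

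Chromosome I carried fewer nuclear peaks than its length predicts. It held 63 of 586 (10.8%, exact 95% interval 8.36 to 13.5%) against 15%, a ratio of 0.715 (two-sided exact binomial test, adjusted p = 0.0188 over 6 chromosomes). In the lists of replicates 1 and 2 alone the ratio was 0.797 and 0.928, with adjusted p of 0.255 and 0.587. Chromosomes II (108 peaks, ratio 1.21) and III (100 peaks, ratio 1.24) had an adjusted p of 0.0669, and IV and V had ratios of 1.02 and 0.981. Chromosome II passed in the ce10 list and in replicate 2 alone (ratios 1.28 and 1.29, exact binomial test, adjusted p = 0.0324 and 0.0202). With coding genes as the expectation III passed with a ratio of 1.29 and V with 0.819, both with an adjusted p of 0.0228. The X chromosome held 91 peaks, a ratio of 0.879 by length (exact binomial test, adjusted p = 0.290) and of 1.14 (adjusted p = 0.279) when coding genes set the expectation.

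Within the autosomes, peaks gathered towards the centres. The outer parts of the 5 autosomes, which make up 66.7% of their length, held 225 of 495 peaks (45.5%, exact 95% interval 41.0 to 50%, exact binomial p = 4.70e-22). Starts of protein-coding genes lay in these parts in 61.9% of cases, and against that share p was 1.57e-13, a comparison added after the data were seen. Peaks were counted as independent, which understates the error.

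Genes for cytosolic ribosomal proteins had a peak at their start more often than other coding genes. A summit within 500 bp of the start was found for 7 of 81 (8.64%, exact 95% interval 3.55 to 17%), against 0.965% of 19904 other coding genes (Fisher's exact test, adjusted p = 8.96e-05 over 22 lists). The 4 with the highest signal were rpl-3 (163), rpl-15 (95.9), rpl-20 (90.4) and rpl-35 (71.3), all of the large subunit. The others were rps-19, rpl-12 and rps-12. The summit counted for rpl-20 lay at -301 bp from its start, and at -161 bp from that of another coding gene. With a window of 250 bp the list no longer passed (Fisher's exact test, adjusted p = 0.295).

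The cuticle and hypodermis list, which holds structural genes of the outer covering, had 12 of 241 members with a peak (4.98%, exact 95% interval 2.6 to 8.54%), against 0.947% of other coding genes (Fisher's exact test, adjusted p = 4.15e-05). All 12 were collagen genes, and they had 11 peaks among them, since col-159 and col-160 shared the highest (chromosome V, 13202191 to 13202580, signal 60.8). col-122 (44.7) and col-129 (43.8) came next. Most of these peaks were below the median signal, and among peaks at or above it the list did not pass (Fisher's exact test, adjusted p = 0.695).

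Among RNA genes, 39 of 634 tRNA genes had a peak (6.15% against 1.22% of other genes, Fisher's exact test, adjusted p = 1.98e-14), of which 22 were mitochondrial. The 4 highest, WBGene00014461, WBGene00014462, WBGene00014463 and WBGene00014464, all lay within reach of the CYTB summit. Shifted summits reached 24.8 tRNA genes on average against the 39 found, a ratio of 1.57 (permutation test, adjusted p = 0.00147). Without mitochondrial peaks they reached 3.43. Most mitochondrial tRNA genes would thus have a peak wherever these summits fell, and the Fisher p overstates the excess. Among nuclear peaks 17 tRNA genes at 12 peaks remained (2.68% against 1.17%, Fisher's exact test, adjusted p = 0.0103), led by WBGene00022903 on chromosome IV with a signal of 86.8, chosen after its value was seen. These 17 were 4.96 times the 3.43 reached by shifted summits (permutation test, adjusted p = 0.00147). Shifting also removes the preference of summits for gene starts of any kind. Among the nuclear peaks in the top 611 of replicates 1, 2 and 3 the count was 15, 15 and 46, with adjusted p of 0.00935, 0.0495 and 6.60e-20. The difference between replicates was not tested. With only the nearest start of each nuclear IDR summit counted, 10 tRNA genes remained and the list did not pass (Fisher's exact test, adjusted p = 0.192).

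Small nucleolar RNA (snoRNA) genes, whose products guide the chemical modification of other RNAs, had a peak in 13 of 346 cases (3.76% against 1.29%, Fisher's exact test, adjusted p = 0.00326). The highest were C04A2.16 (signal 101), T03F7.8 (69.8), K02F3.15 (62.8) and D1046.6 (49.4), and F54E7.10 shared its peak with rps-12. In replicate 1 alone 4 had a peak and the list did not pass (Fisher's exact test, adjusted p = 1), nor did it among peaks at or above the median signal, where the ratio of shares was 2.65 after 2.92 (adjusted p = 0.158). Genes of piRNAs, small RNAs of the germline, had a peak less often, in 44 of 15363 cases at 20 peaks (0.286% against 1.31%, Fisher's exact test, adjusted p = 2.29e-30). These genes lie close together, and against shifted summits the adjusted p was 0.0962 in a permutation test.

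The other 17 lists did not pass in the main test. Small nuclear RNA genes had 5 of 129 with a peak (adjusted p = 0.103), led by sls-2.2 (87.6) and sls-2.1 (75.1), which encode spliced leader RNAs; against shifted summits the list passed, with an adjusted permutation p of 0.0326, as it did with a window of 1000 bp and in replicate 3 alone (Fisher's exact test, adjusted p = 0.0339 and 0.0390), and among nuclear peaks of replicate 1 (0.0368). The microRNA genes had 7 of 261 (Fisher's exact test, adjusted p = 0.218), led by mir-4929 and mir-52, and passed with a window of 1000 bp and in replicate 2 alone (adjusted p = 0.0143 and 0.0323). Translation factors had 2 of 45 (iff-2 and pab-2) and nuclear genes of oxidative phosphorylation 2 of 47 (cox-5A and cox-5B), both with an adjusted p of 0.218. In replicate 1 alone the translation factors had 4 and passed (Fisher's exact test, adjusted p = 0.00398).

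None of the 5 germline gene lists passed. The germ granule and RNA regulator list had 1 of 44 (puf-9) and the sperm list 1 of 93 (spe-54), while none was found for 38 small RNA pathway, 43 meiotic chromosome and 24 oocyte and eggshell genes. Exact 95% upper limits for these 3 were 9.25%, 8.22% and 14.2%, against 0.998%, 0.998% and 0.997% of other coding genes. Even a large excess could therefore not be excluded for any of these lists. A single member had a peak in the lists of 72 core histone (his-37), 137 neuronal (nlp-33), 39 muscle (unc-112) and 325 intestinal genes (clec-126). None had one in those of 33 proteasome, 56 splicing, 26 heat shock and 5 Y-box and cold shock genes. List membership does not show where a gene is expressed. The nlp-33 summit lay downstream of the gene, at 459 bp from its start. The clec-126 summit was also within 500 bp of tRNA gene starts. In the main test the adjusted p of these 13 lists ran from 0.709 to 1, and none reached an unadjusted p under 0.05. With a window of 1000 bp the germ granule and RNA regulator list had 3 of 44 with a peak (6.82% against 1.49%). Its unadjusted p was then 0.0284 and its adjusted p 0.0782 (Fisher's exact test), and with 250 bp it had 0.

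**Figure D3:**
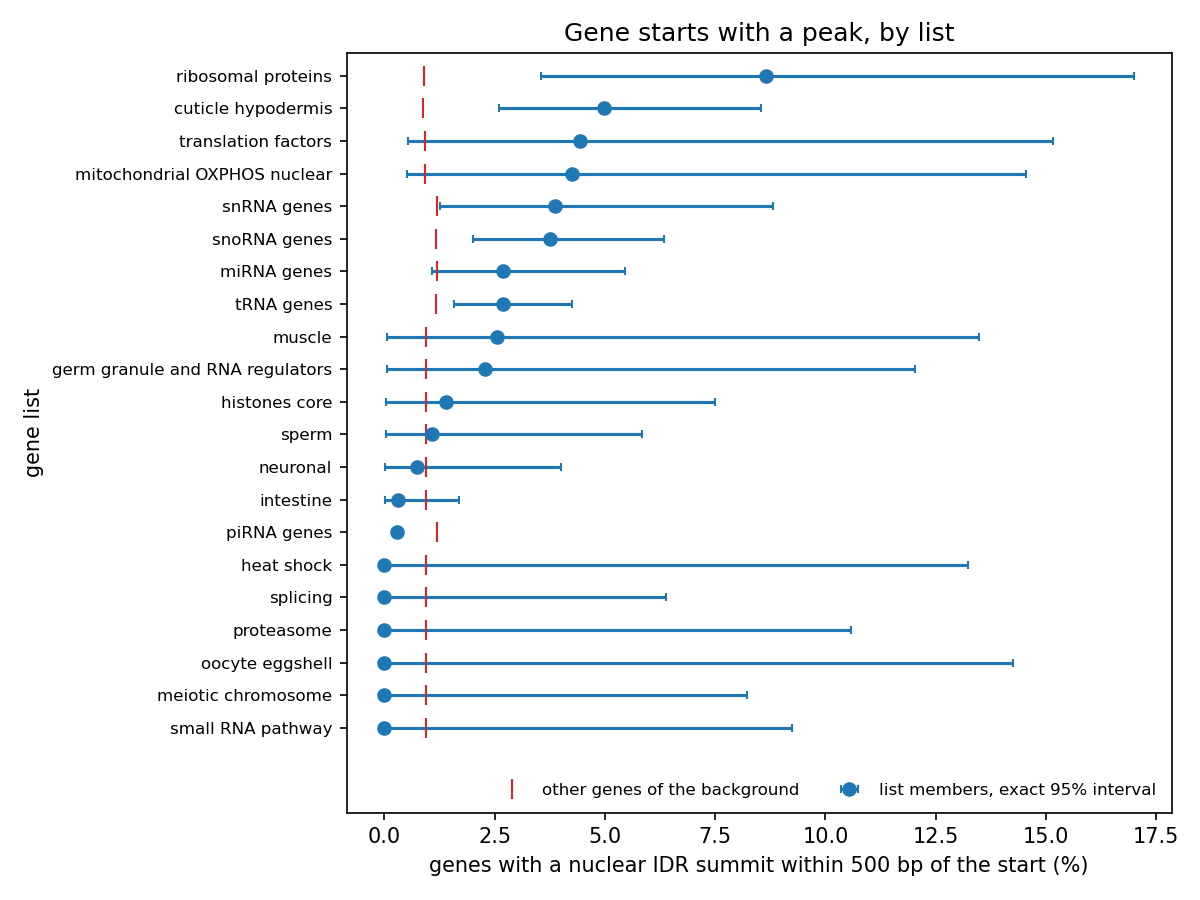
Points give the share of each list's members (%) with a nuclear IDR summit within 500 bp of the start, with exact 95% intervals, and ticks the share of other genes of the same background. Ribosomal protein genes stand at 8.64% and the cuticle and hypodermis list at 4.98%; the 5 Y-box and cold shock genes are left out of the plot.

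Certain short sequence words were more frequent at summits than beside them. The word GAGAGA occurred within 100 bp of 41.2% of summits and in 9.17% of flank windows 500 bp away (exact McNemar test, adjusted p = 2.49e-37 over 11 words). The E-box CACGTG occurred in 19% against 2.95% (exact test, adjusted p = 1.07e-20) and TGATAA, a site of GATA factors, in 40.6% against 17.5% (adjusted p = 2.75e-17). CGCG (29.1% against 15.4%) and CACACA (22.4% against 10.6%) were also more frequent, with adjusted p of 4.77e-09 and 1.05e-07.

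The CCAAT word, the core of the Y-box after which the protein family is named, was less frequent at summits than in flanks. It occurred in 28.8% against 35.5% (exact McNemar test, adjusted p = 0.0218), and it did not pass among nuclear peaks (adjusted p = 0.0810), among peaks at or above the median signal (0.380) or in replicates 1 and 2 alone (1 and 0.557). TATAAA was also less frequent (19.1% against 26.5%, exact test, adjusted p = 0.00375), but not with flanks 1000 bp away (adjusted p = 0.206) or in replicates 1 and 3 alone (0.785 and 0.383). The TTCCCGC word was found in 3.44% against 1.31% (exact test, adjusted p = 0.0332), and it did not pass among nuclear peaks (adjusted p = 0.479), within 50 bp of the summit (0.294) or in replicates 2 and 3 alone (0.0644 and 0.303). Flank sides were drawn anew for each set of peaks. Runs of TTTTTTTT, the AP-1 site and the B box of tRNA gene promoters did not pass, with adjusted p of 0.887, 0.712 and 0.384. The B box passed in replicate 3 alone (12.8% against 7.36%, exact test, adjusted p = 0.00319) and among peaks at or above the median signal (adjusted p = 0.0186).

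Summit windows had a mean GC content of 39.9% against 34.2% in flank windows. The paired difference was 5.64 ± 0.380 percentage points (SE over 611 peaks), and GC content was higher at the summit in 444 of 611 peaks (two-sided sign-flip permutation test of 100000 draws, p = 1e-05, the smallest possible). In the top 611 peaks of replicates 1, 2 and 3 the difference was 2.95, 6.90 and 3.70 points.

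**Figure D4:**
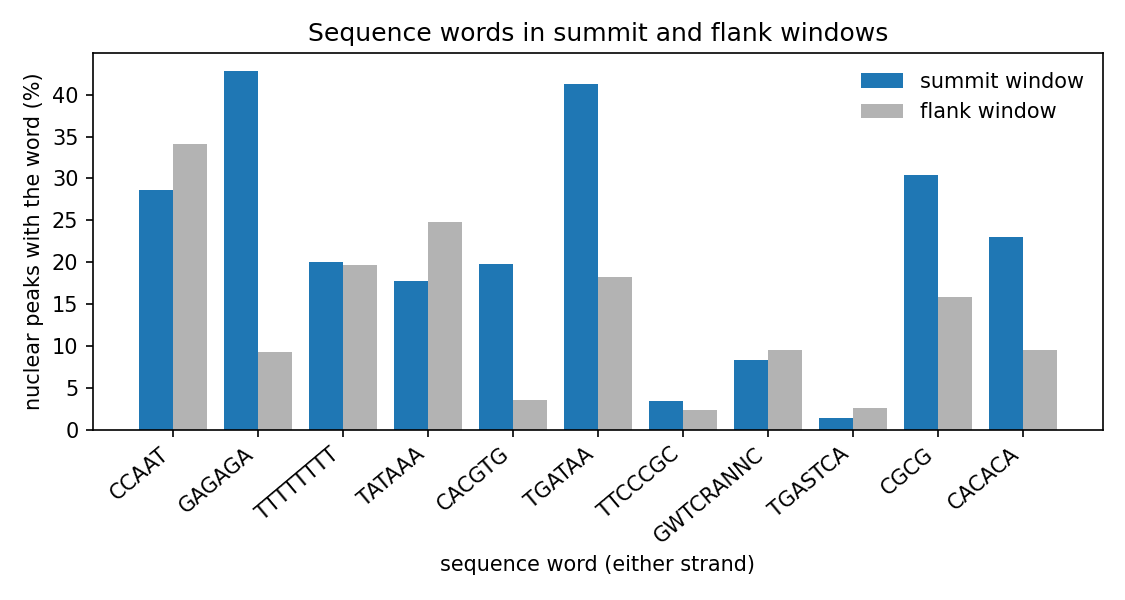
Bars give the share of the 586 nuclear peaks (%) with each sequence word in the window around the summit and in 1 flank window. GAGAGA stands at 42.8% against 9.22% and CCAAT at 28.7% against 34.1%.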

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

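Of the values that answer a comparison, 73 kept their direction and their side of the threshold, or stayed within the allowed range, under an alternative, 5 moved and 6 reversed. Among single classes, chromosomes, lists and words, 351 were the same, 27 no longer passed, 17 newly passed and 39 reversed. The cause was not tested unless stated. Alternatives with nuclear peaks only, in mitochondrial regions, of transgene loci by replicate, of coding starts in the outer parts of autosomes, or of words, GC content and signal in single replicates were chosen after seeing the data. Depth is unknown for every list, so it cannot be said whether differences between replicates follow from it.

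Keeping peaks at or above the median signal left 306 peaks, by construction fewer, and 3 passing lists. The ratio of shares went there from 5.26 to 1.64 for the cuticle and hypodermis list, from 2.92 to 2.65 for snoRNA genes and from 8.96 to 15.4 for ribosomal protein genes, and the cause was not tested. Merging left 15 mitochondrial regions. Without 1 replicate, the overlap ran from 34% to 38.5% and rho from 0.174 to 0.256 (mean of pairs 0.222), and for nuclear peaks the mean rho was 0.151. The X ratio reversed to 1.14 with coding genes as expectation. The promoter minus other signal reversed to -1.34 (250 bp promoters), -0.671 (1000 bp), -0.00672 (nuclear), -0.350 (replicate 2) and -0.118 (replicate 3), none with a p under 0.05.

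The 3′ UTR share reversed to 4.26% (replicate 1) and 3.44% (replicate 3), above their shifted shares. Chromosome IV reversed to 0.996 (median signal), 0.848 (replicate 2) and 0.965 (replicate 3), and V to 1.05 (median signal), 1.07 (replicate 1) and 1.10 (replicate 3). Ratios of shares with a peak, in lists that did not pass, reversed to 0 for germ granule, sperm and muscle genes at 250 bp, for muscle at the median signal and in replicate 1, and for oxidative phosphorylation in replicate 3. They reversed to 2.77 (oocyte), 2.56 (heat shock) and 0.922 (histones) at 1000 bp, and to 1.25 for neuronal genes against shifted summits. In replicate 1 they reversed to 3.17 (proteasome) and 4.02 (heat shock), in replicate 2 to 1.83 (splicing), and in replicate 3 to 3.60 (heat shock) and 1.37 (neuronal). With nuclear peaks these were 3.38, 4.29, 1.94, 3.82 and 1.45, and 0 again for muscle and oxidative phosphorylation. Word ratios reversed for the T run to 0.884 (50 bp), 0.879 (median signal), 0.908 (replicate 2) and 0.896 (replicate 3), for the B box to 0.813 (flank 1000 bp away), 0.853 (nuclear) and 0.955 (replicate 1), and for AP-1 to 2.23 (replicate 2) and 1.93 (replicate 3).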

Other observations

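Chosen after the results were seen were the comparisons of gene types and of clusters, the test of mitochondrial heights between replicates, the tests of shared starts and of germline genes, and the letter orders in other settings, while the tests of GC content and of letter orders in the main setting were written before their values were computed.

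Nuclear noncoding RNA genes had a peak at their start more often than other genes. Of 7764 genes annotated only as noncoding RNA, 139 (1.79%, exact 95% interval 1.51 to 2.11%) had a nuclear summit within 500 bp, against 1.01% of other genes without piRNAs (Fisher's exact test, adjusted p = 5.38e-07 over 11 gene types). Pseudogenes had one in 7 of 2128 cases (0.329%, Fisher's exact test, adjusted p = 4.99e-05) and protein-coding genes in 187 of 19985 (0.936%, adjusted p = 1.49e-07), both less often than other genes. Many noncoding RNA genes lie near coding genes, so that 1 summit counts for several starts. With only the nearest start of each summit within 500 bp counted, noncoding RNA genes kept a smaller excess (85 genes, 1.09% against 0.752%, Fisher's exact test, adjusted p = 0.0168), pseudogenes stayed lower (4 genes, adjusted p = 0.00109) and coding genes no longer passed (0.746% against 0.993%, adjusted p = 0.0525).

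Nuclear peaks lay in clusters. Of 586, 197 (33.6%) had another within 10 kb, against 13.5% of as many peaks drawn at random from the 25458 nuclear peaks of the pooled list (one-sided permutation test of 10000 draws, p = 0.0001, the smallest possible). The regions with the most peaks, all named after their values were seen, had 5 each. One lay on chromosome IV at 8527695 to 8535358 inside pkg-2, upstream of hyl-1. Another lay on chromosome II at 10543354 to 10563779 around mnk-1 and cdc-48.1, and the last on the X chromosome at 6736314 to 6750478, over R03E9.10 and abts-4. Other regions, with 4 peaks each, lay over zfp-1, ifbp-1, let-526 and nhr-31.

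Of the 25 mitochondrial peaks, 22 had a summit within 200 bp in the lists of both replicates 1 and 2, 21 in 1 and 3, and 20 in 2 and 3. Many such matches arise by chance on this short molecule, since shifted overlaps of replicates 1 and 2 fell from 2.78% to 0.240% without mitochondrial peaks. Recurrence of place was not tested. The heights of these peaks could come from the DNA present rather than from the tagged protein. If the excess of mitochondrial DNA and the control were both even along the molecule, only the noise of each library would order the heights. Spearman's rho between replicates averaged 0.542 over the peaks (0.625, 0.574 and 0.427, one-sided permutation test of 10000 draws, p = 0.0002). Over the 15 distinct regions rho averaged 0.693 (one-sided permutation test of 10000 draws, permutation p = 0.0001, the smallest possible). These values argue against library noise alone as the source of the order. They do not argue against an excess of mitochondrial DNA, whose order of heights could recur through a sequence bias or an uneven control. GC content is a candidate explanation of the heights: over the 25 peaks it had a rho of 0.469 with the signal (95% bootstrap interval 0.0344 to 0.755, two-sided permutation p = 0.0193), as a sequencing or shearing bias would give. The 25 peaks were taken as independent here, although they form only 15 distinct regions. This interval and p therefore understate the error, and GC content was not compared over the regions. Unevenness of the control would also recur in every list called against it, and this stays open. No biological explanation was tested, since the design has 1 group and the control was not analysed here.

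The sequence words could follow from the higher GC content of summit windows. If base composition alone were the cause, other orders of the same letters would have ratios of peaks with the word only at the summit to those with it only in the flank as high, and this held for 0 of 18 for GAGAGA (7.43 against a highest of 2.74), 0 of 101 for CACGTG (9.52 against 3.36), 0 of 59 for TGATAA (3.06 against 1.73) and 0 of 18 for CACACA (2.40 against 1.75). Ratios changed with the setting, from 3.22 in replicate 1 to 10.7 in replicate 2 for GAGAGA, and with flanks 1000 bp away the margin was narrower (4.03 against 3.06 for GAGAGA, 4.91 against 4.33 for CACGTG, 2.45 against 2.25 for TGATAA), but no other order of these 3 words was as high in any of 7 other settings, which argues against base composition alone. For CACACA none was as high in 5 of the 7, but 2 of 18 were within 50 bp of the summit and 1 of 18 in replicate 1, so that base composition cannot be told apart from a preference for this order. CGCG has too few other orders to be tested, and whether the words mark sites of the tagged protein or accessible regulatory sequence in general stays open.

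The peaks at ribosomal protein, collagen, tRNA and snoRNA genes could arise where closely packed starts share 1 summit. Only the nearest start of each nuclear summit was counted, among coding genes for coding lists and among genes without piRNAs for RNA lists. A peak was then left for 5 of 81 ribosomal protein genes, 10 of 241 cuticle and hypodermis genes and 9 of 346 snoRNA genes. The adjusted p of Fisher's exact test was 0.00481 for ribosomal protein genes, 0.000491 for the cuticle and hypodermis list and 0.0148 for snoRNA genes. These values argue against shared summits as the whole cause. They do not show that the tagged protein was the cause, since the control was not analysed here. For the coding lists they cover only summits shared between coding genes, and sharing with noncoding genes stays open. With tRNA starts within 1000 bp of each other merged to 1 locus, and other starts alike, 12 of 480 tRNA loci (2.5%, exact 95% interval 1.30 to 4.33%) against 1.13% of 22764 other loci had a nuclear peak (Fisher's exact test, p = 0.0140), which argues against packing of tRNA genes next to each other as the whole cause. Summits shared with starts of other genes cannot be told apart from an excess at tRNA genes: by nearest start 10 remained, 1.58% (exact 95% interval 0.759 to 2.88%) after 2.68% (1.57 to 4.26%), with a ratio of 1.92 after 2.29 and an adjusted p of 0.192, the count being too low to decide. A hypothesis that the peaks mark germline genes gave an odds ratio of 0.885 for the 5 germline lists together (95% interval 0.106 to 3.28; 2 of 241 genes against 185 of 19744), too wide to decide.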
